A study of Mus musculus with 6 samples.

How the data were processed

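RNA from mouse colonic mucosa was hybridised to Affymetrix 3' expression arrays, 3 labelled p38a knockout and 3 labelled wild type, after extraction with Trizol, a column clean-up and labelling with a 3' in vitro transcription kit, per the labels' protocols. The deposited table holds 1 linear intensity per probe set and array for 45101 probe sets, computed with MAS5 per the submitters' processing notes. MAS5 condenses the probes of a set into 1 signal, and a scaling of each array to a common target is an option of it. The version, target and scaling used by the authors are not given in the sources used here. All values were above 0, and replicates were not pooled.

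The design fixed before the data were examined assumed signals already scaled by the authors and planned no normalization between arrays. The values contradicted this, because the 2% trimmed mean differed between arrays, from 117 in wild type C to 222 in the array labelled knockout A, where a common target would give equal means. Quantile normalization, which had been planned as an alternative, was therefore taken as the main setting before any test was run, and the fit on the signals as deposited is given beside it. Quantile normalization gives all arrays 1 distribution and removes any overall difference in RNA content between groups. A difference in RNA quality that affects transcripts unequally stays in the values. The ratio of the 3' to the 5' Gapdh control probe set on the deposited signals was used as a measure of RNA quality.

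Signals were taken as log2(signal + 16), a pseudocount of 16, and quantile normalized in limma over all probe sets. Probe sets with a mean under the 40th percentile were dropped, which left 27061, corresponding to a signal of about 18.4 or more. The 64 control probe sets were left out of the tests. Gene symbols came from the platform annotation, where 34945 probe sets had 1 symbol, 932 several and 9160 none here, and no symbol changed when updated through the gene identifiers. Probe sets with several symbols or none were not named. Of 22490 named probe sets above the filter, the brightest of each gene was kept, which gave 12437 genes. Probe sets whose suffix marks possible cross-hybridisation, among them those of Mt1, Trim15, Saa2, Ang4 and Gstm1, may read related transcripts as well.

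The groups were compared with lmFit and eBayes with a variance trend (limma 3.58.1 in R 4.3.3; 4 residual and 4.19 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. A count of genes at least 2-fold apart (log2 difference of 1 or more) with no overlap between the groups was made beside it. Mapk14 was also compared with an exact two-sided permutation test. Fixed before the data were examined were 42 gene lists of pathways and cell types, of which 39 had at least 5 tested genes; 73 listed symbols had no named probe set here. Lists were tested with camera in limma, preset correlation 0.01, with an estimated correlation and fry beside it. camera asks whether a list moved relative to all other genes. fry asks whether its genes moved, on balance, 1 way. Figures were drawn from these values.

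Genes were named by a rule fixed before the data were examined. Mapk14 and its paralogs were always named. In each direction 12 genes were named, first those past the threshold with separate groups by size, and, as none passed, those with the smallest unadjusted p among genes at least 2-fold apart. Up to 4 members of each described list with the smallest unadjusted p were added. Muc2, Lyz1, Reg4, Kit, Mmp7, Reg3b, Reg3g, Mt2, Cd274, Ido1, Ak4, Prdm1, Ndrg1, and the genes of lists that were not called were chosen after their values were seen.

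The steps were tested on simulated data, 3 arrays against 3 with 12437 genes, of which 200 per size were changed, in 5 simulations. limma called 51.8% of genes changed by 1 in log2 terms, 92.8% of those changed by 2 and 97.3% of those changed by 3. Of the calls, 5.88% were unchanged genes. The noise followed limma's fitted variances, with no differences between arrays that genes share, and many planted changes ease the adjusted threshold. These shares therefore do not tell how many changed genes were missed in the real data. camera gave a p under 0.05 for 100% of lists of 20 genes shifted by 0.5 and 0% of unshifted lists. The genes of a simulated list were independent of each other, unlike genes that move together between arrays. The share for unshifted lists therefore does not tell how often the preset correlation calls such lists in the real data.

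Alternatives planned before the data were examined were other scalings (as deposited, centred on array medians), pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, the mean of a gene's probe sets or every probe set, eBayes without a trend or with a robust prior, array weights, the replicate letter as a block, each array left out in turn, an estimated correlation in camera, and fry. Added after seeing the data were 3 more, namely scaling to a common trimmed mean, wild type B as the only control, and the log2 Gapdh ratio as a covariate. For goblet and tuft genes camera with an estimated correlation and fry were also run with that covariate. Gene order along the chromosome came from the RefSeq annotation of the GRCm38.p6 assembly, whose start positions were used only to order the genes.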

Results

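Gene expression in the colonic mucosa of C57BL/6 mice was measured on Affymetrix 3' expression arrays. There were 3 arrays labelled p38a knockout and 3 labelled wild type, each with the letters A, B and C. p38a is the stress-activated kinase encoded by Mapk14, and the labels name intestinal epithelial cells as the cell type and no treatment. The comparison asks which transcripts differ in the colonic mucosa between the samples labelled p38a knockout and wild type. The labels do not say that the samples came from separate animals, so no p-value can be taken to measure the spread between animals. The p-values of single genes measure only the spread between these samples, which may be technical. Those of camera with its preset correlation set a list against all other genes. They do not estimate how the genes of a list move together between arrays, for which the estimated correlation is given beside them. For arrays there is no count depth, and their number limits the precision. Values below are log2(signal + 16) after quantile normalization, so fold changes on this scale understate the change of dim genes.

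The wild-type arrays A and C were dimmer than the rest. The trimmed mean of the deposited signals was 141 in wild type A and 117 in wild type C, against 188 in wild type B and 222, 192 and 203 in the arrays labelled knockout A, B and C. The ratio of the 3' to the 5' Gapdh control signal, which goes up as RNA is degraded, was 1.10 and 1.45 in wild type A and C. It was 0.989 in wild type B and 0.907, 0.954 and 0.859 in the arrays labelled knockout. Brightness and the Gapdh ratio therefore moved with the genotype label, and wild type B stood closest to the arrays labelled knockout. The same ratio for the actin gene Actb was 2.40, 2.24 and 3.25 in wild type A, B and C. In the arrays labelled knockout A, B and C it was 2.05, 2.27 and 1.82. By Actb the groups overlapped, wild type C stood out, and wild type A lay close to the array labelled knockout B.

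**Figure D1:**
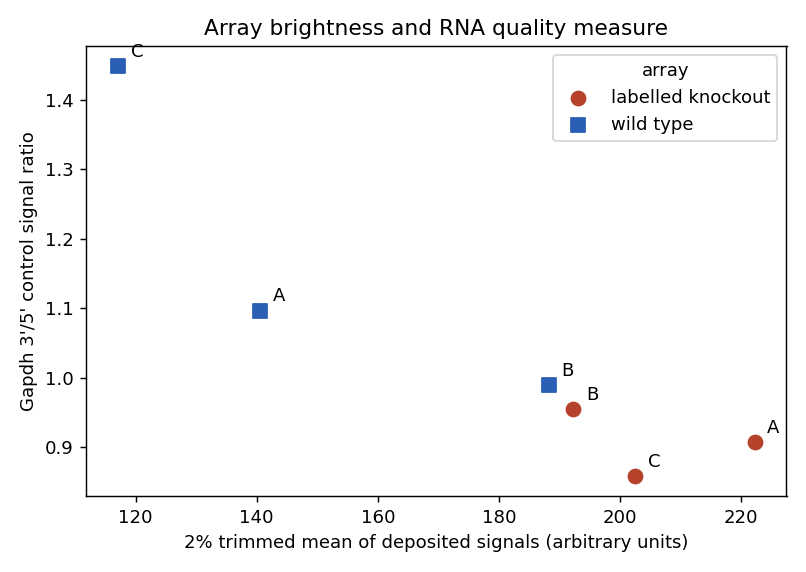
Each point is 1 array, with the 2% trimmed mean of its deposited signals (arbitrary units) on the x axis and the ratio of its 3' to 5' Gapdh control signals on the y axis; letters are the replicate letters. Wild type A and C, at trimmed means of 141 and 117, have the highest ratios, 1.10 and 1.45.

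Mapk14 itself was not lower in the arrays labelled knockout. Its brightest probe set read 9.79 ± 0.11 (SD, n = 3) there and 9.37 ± 0.06 (SD, n = 3) in wild type, a log2 difference of 0.41 (SE 0.14, limma adjusted p = 0.902). All 3 arrays labelled knockout (9.72, 9.91 and 9.73) lay above all 3 wild-type arrays (9.31, 9.44 and 9.37), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays can give. Of the 6 Mapk14 probe sets 1 was lower, by -0.07 in log2 terms, and the others were higher by 0.17 to 0.62. Apart from the brightest, the groups overlapped on every probe set (exact two-sided permutation p from 0.3 to 0.9), and 1 lay below the signal filter. The signal of the brightest probe set thus went against the label, and "the arrays labelled knockout" is used throughout for that reason. A 3' probe set outside the deleted part checks nothing, and the position of these probe sets against the deleted part was not used here.

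The related kinases gave no call. The Mapk12 difference was -0.55 (SE 0.41, limma adjusted p = 0.902) and the Mapk13 difference -0.18 (SE 0.29, limma adjusted p = 0.910), and Mapk11 lay below the signal filter. Both directions turn with the Gapdh ratio as a covariate, to 0.13 for Mapk12 and 0.36 for Mapk13, and that of Mapk13 also turns to 0.13 without wild type C. On the signals as deposited Mapk13 read 0.27, which is below the median of all genes in that setting, 0.43. Of 29 tested genes of the p38 pathway 13 were higher and 16 lower, and the list was not called (camera adjusted p = 0.593). No member passed over all genes tested or adjusted over the list alone. Besides Mapk14, the smallest p-values among them belonged to Map2k6, an activator of p38, at 0.84 (SE 0.25), Zfp36, which encodes an mRNA-destabilising protein, at -0.86 (SE 0.31), and Dusp1, a phosphatase that inactivates p38, at -1.09 (SE 0.45). With wild type B as the only control Map2k6 read 0.37, Zfp36 -0.21 and Dusp1 0.03, and with the Gapdh ratio as a covariate 0.37, -0.10 and 0.07, so that Dusp1 turned in both.

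The metallothionein gene Mt1, whose product binds zinc and other metals, had the smallest p of all genes tested. Its signal was 12.98 ± 0.25 (SD, n = 3) in the arrays labelled knockout and 10.65 ± 0.40 (SD, n = 3) in wild type, 5.02-fold higher (log2 difference 2.33, SE 0.22), with an adjusted p of 0.0507 in limma. Its other probe set went the same way. Rbp2, which encodes a cellular retinol-binding protein of the intestine, was 2.56-fold higher (log2 difference 1.35, SE 0.18, limma adjusted p = 0.213), from 4.54 ± 0.11 to 5.89 ± 0.06 (SD, n = 3 each), close to the bottom of the scale. Tmem14a stood at 1.44, Ms4a10 at 1.24, Slc6a20a, an amino acid transporter gene, at 1.20 and Timp4, a metalloproteinase inhibitor gene, at 1.17, with no overlap between the groups. Slc10a2, the ileal bile acid transporter gene, stood at 1.35, Cyp2c68 at 1.25, Oxa1l at 1.15, Tcf7l1 at 1.06, the smooth muscle gene Tagln at 1.04 and the glutathione transferase gene Gsta3 at 1.02. Among these 6, only for Tagln did the groups not overlap. Single arrays weighed on some of these values. Tagln read 6.88 in the array labelled knockout A, 5.20 in B and 5.64 in C, against a wild-type mean of 4.86. Cyp2c68 read 7.67 in the array labelled knockout A, 9.01 in B and 9.64 in C, against a wild-type mean of 7.53. For Tcf7l1 and Oxa1l another probe set went the opposite way. With wild type B as the only control the differences shrank to 0.06 for Gsta3, 0.18 for Oxa1l, 0.46 for Tcf7l1, 0.72 for Timp4 and 0.79 for Tmem14a, and with the Gapdh ratio as a covariate to 0.25 for Gsta3, 0.38 for Oxa1l, 0.52 for Tcf7l1, 0.54 for Slc6a20a and 0.87 for Tmem14a, while that of Slc10a2 was 2.05.

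Of the 12 genes named on the lower side none passed in limma. Clps, which encodes the lipase cofactor colipase, was 4.11-fold lower (log2 difference -2.04, SE 0.24, limma adjusted p = 0.136), at 6.53 ± 0.43 in the arrays labelled knockout against 8.57 ± 0.02 in wild type (SD, n = 3 each). Pnliprp2, a pancreatic lipase-related gene, was 6.41-fold lower (log2 difference -2.68, SE 0.47, limma adjusted p = 0.876), and Pla2g4c, a phospholipase A2 gene, was 3.77-fold lower (log2 difference -1.92, SE 0.25, limma adjusted p = 0.200). The other probe set of each of these 3 genes went the same way. Transcripts of the pancreas were seen in wild type B, where the median of 8 other pancreatic enzyme genes lay 2.19 above the arrays labelled knockout, but in wild type A and C that median was -0.12 while Clps was 2.05 higher. Bmp8b stood at -1.32, Csta1 at -1.36, Ly6m at -2.33, the membrane mucin gene Muc1 at -1.51 and Cd55, a complement regulator gene, at -1.33. Ppm1j stood at -1.49, Trim15 at -1.16, Clca4c-ps at -1.23 and 2310079G19Rik at -1.52, and in these 9 genes no array of 1 group reached into the other group. With wild type B as the only control the differences were smaller in size for Trim15 (-0.50), Ppm1j (-0.62) and Ly6m (-1.39), and with the Gapdh ratio as a covariate for Clca4c-ps (-0.47), Trim15 (-0.62), Ppm1j (-0.66), Csta1 (-0.83), Cd55 (-0.84) and Ly6m (-1.31).

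Over all genes, limma called 0 of 12437 at an adjusted p of 0.05, and 490 had an unadjusted p under 0.05, 216 higher and 274 lower. Of 36 genes at least 2-fold apart with no overlap between the groups, 7 were higher and 29 lower. In all, 1127 genes (9.06%) had no overlap, where chance gives 10%. On the signals as deposited, with no scaling between arrays, limma called 1 gene, Mt1, and the unadjusted split was 2085 higher against 39 lower, because the median of all genes lay 0.43 higher in the arrays labelled knockout. These counts changed when 1 array was left out. limma called 6 genes without wild type B (Ak4, Mt1, Prdm1, Ndrg1, Tmem14a and Cd274) and 1 without wild type C (Mt1). The 2-fold count was 80 without the array labelled knockout B, 101 without C and 267 without wild type B. Groups of 2 against 3 arrays separate more easily, so these 2-fold counts cannot be set directly against 36. The share of all genes with no overlap was 16.8%, 19% and 36.8% in these settings, against 9.06% with all arrays. Among the named genes, 41 of 77 were smaller in size by over 1.5 times or turned with wild type B as the only control, and 42 of 79 with the Gapdh ratio as a covariate. Most of these genes were named for a small p in the main setting, so part of such shrinkage can come from that choice alone. Genes not chosen that way were not counted, so the counts do not tell which arrays carry the differences.

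**Figure D2:**
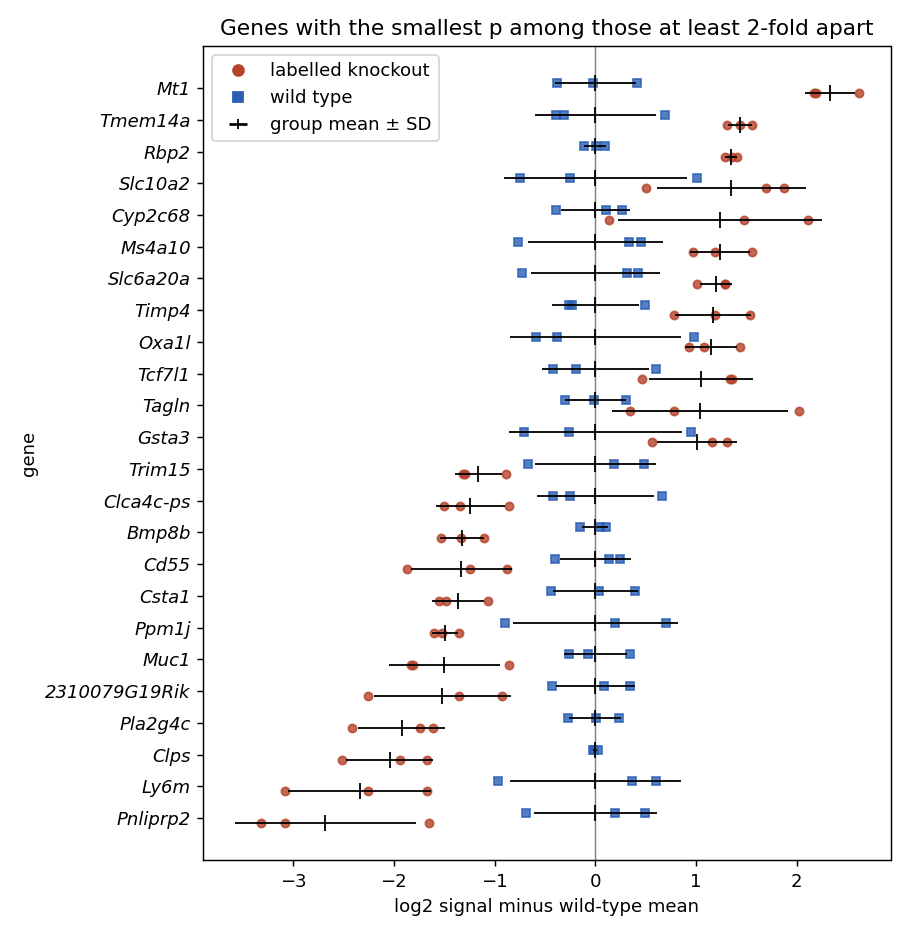
Each point is 1 array's log2 signal minus the wild-type mean (x axis) for the 12 higher and 12 lower genes named by rule (y axis); bars are group means ± SD (n = 3). The 3 arrays labelled knockout lie above wild type for Mt1 (mean difference 2.33) and below it for Clps (mean difference -2.04).

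Goblet and tuft cell genes were lower as groups in the arrays labelled knockout. The lists of enteroendocrine cells (mean -0.22) and of Notch and secretory specification were not called (camera adjusted p = 0.543 each), and whether they differ from the goblet and tuft lists was not tested. The enteroendocrine list was called lower on the signals as deposited (adjusted p = 0.0261) and with a filter at the 60th percentile (adjusted p = 0.0173). Of 21 goblet cell genes, markers of the mucus-secreting cells, 19 were lower, with a median log2 difference of -0.24, and the list was called (camera adjusted p = 4.07e-07; adjusted p = 0.287 with an estimated correlation). Of 13 tuft cell genes, markers of the chemosensory cells, 12 were lower, with a median of -0.42 (camera adjusted p = 8.71e-07; adjusted p = 0.287 with an estimated correlation). In both lists the mean of each array labelled knockout lay below that of each wild-type array. No goblet gene passed over all genes tested and 2 passed adjusted over the list alone, namely Fcgbp, which encodes an IgG Fc-binding mucus protein, at -0.81 (SE 0.21) and the calpain gene Capn9 at -0.77 (SE 0.18). Sytl2 stood at -0.62 and Clca1 at -0.36, and the main mucin gene Muc2 at -0.11 (SE 0.10). With wild type B as the only control Fcgbp read -0.44 and Sytl2 -0.20, and with the Gapdh ratio as a covariate Sytl2 read -0.35. No tuft gene passed over all genes tested and 3 passed adjusted over the list alone, namely Dclk1 at -0.81 (SE 0.21), Rgs13 at -0.998 (SE 0.264) and Ltc4s, the leukotriene C4 synthase gene, at -0.81 (SE 0.23). Avil stood at -0.62. With the preset correlation both lists were called lower under all 21 other settings. On the signals as deposited their medians were 0.10 and -0.09, against the median of 0.43 for all genes.

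The list of Paneth and deep crypt secretory genes was also called lower, with 5 of 8 genes lower, a median of -0.43 (camera adjusted p = 0.00439; adjusted p = 0.287 with an estimated correlation) and the array means of the groups apart. No member passed over all genes and 3 passed adjusted over the list alone. These were Ang4, an angiogenin-family antimicrobial gene, at -0.85 (SE 0.21), Mptx1, a mucosal pentraxin gene, at -1.47 (SE 0.40) and Itln1, an intelectin gene, at -1.53 (SE 0.50), while Lyz1, the Paneth cell lysozyme gene, stood at -0.26 (SE 0.94). Reg4, Kit and Mmp7 on the same list were higher, at 0.31 (SE 0.80), 0.153 (SE 0.345) and 0.12 (SE 0.29). The Paneth call was lost without wild type B (adjusted p = 0.0883). The list of epithelial antimicrobial genes, 4 of whose tested genes are on the Paneth list and 3 on the goblet list, had 16 of 23 genes lower, with a median of -0.22 (camera adjusted p = 0.00439; adjusted p = 0.426 with an estimated correlation). The acute-phase gene Saa2 stood at -1.34 (SE 0.42), Saa1 at -0.40 (SE 0.14), and Reg3b and Reg3g at 0.14 and 0.35. That call was lost without wild type C (adjusted p = 0.0904), with array weights (adjusted p = 0.103), with wild type B as the only control (adjusted p = 0.792) and with the Gapdh ratio as a covariate (adjusted p = 0.784).

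Immune and early-response genes were lower as groups in the mean of the arrays labelled knockout than in wild type A and C. Wild type B lay close to or below that mean. Of 28 interferon-stimulated genes 26 were lower, with a median of -0.40 (camera adjusted p = 4.07e-07; adjusted p = 0.796 with an estimated correlation), including Oas2 at -1.21 (SE 0.39), Ifit1 at -1.20 (SE 0.42) and Irf7, an interferon-response transcription factor gene, at -0.99 (SE 0.37). All 14 T cell genes were lower, with a median of -0.50 (camera adjusted p = 0.00112; adjusted p = 0.796 with an estimated correlation), among them the T cell receptor complex gene Cd3e at -1.01 (SE 0.36). Of 20 AP-1 and immediate early genes 15 were lower, with a median of -0.27 (camera adjusted p = 0.000391; adjusted p = 0.796 with an estimated correlation), including Ier5 at -0.98 (SE 0.29) and the stress-response factor gene Atf3 at -0.96 (SE 0.38). Of 22 inflammatory and NF-kB target genes 16 were lower, with a median of -0.24 (camera adjusted p = 0.00468; adjusted p = 0.796 with an estimated correlation), with Tnf at -1.02 (SE 0.29), the chemokine gene Cxcl1 at -0.73 (SE 0.23) and Ccl28, a mucosal chemokine gene, at 0.63 (SE 0.23). No member of these 4 lists passed over all genes or adjusted over the list alone.

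The mean of the interferon list in the arrays labelled knockout differed by -0.76 from wild type A and C, whose Gapdh ratios were the highest, and by 0.02 from wild type B. For the T cell list these differences were -0.93 and 0.35, for the AP-1 list -0.48 and 0.06, and for the inflammatory list -0.40 and 0.04. With wild type B as the only control the interferon, AP-1 and inflammatory calls were lost (adjusted p = 0.537, 0.268 and 0.8), and with the Gapdh ratio as a covariate they were lost as well (adjusted p = 0.779, 0.880 and 0.290). The T cell list was called higher in both settings (adjusted p = 0.0328 and 3.59e-05), with Cd3g moving from -0.681 to 0.465 and 0.595. Its call was also lost without the array labelled knockout A (adjusted p = 0.0745) and without wild type C (adjusted p = 0.171). The inflammatory call was lost without the arrays labelled knockout A (adjusted p = 0.0745) or C (adjusted p = 0.0575) and without wild type C (adjusted p = 0.0866).

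Mitochondrial and glutathione genes were higher as groups. Of 24 oxidative phosphorylation genes 19 were higher, with a median of 0.12 (camera adjusted p = 0.0021; adjusted p = 0.796 with an estimated correlation), including the ATP synthase subunit gene Atp5c1 at 0.37 (SE 0.12) and Ndufs3 at 0.27 (SE 0.15). Of 22 NRF2 and glutathione genes 19 were higher, with a median of 0.16 (camera adjusted p = 0.00249; adjusted p = 0.426 with an estimated correlation), including the glutathione transferase gene Gstm1 at 0.68 (SE 0.21) and Nqo1, a quinone reductase gene, at 0.56 (SE 0.28). No member of either list passed over all genes or adjusted over the list alone. Both calls were lost with wild type B as the only control (adjusted p = 0.240 and 0.124) and with the Gapdh ratio as a covariate (adjusted p = 0.233 and 0.0828). The oxidative phosphorylation call was also lost without the array labelled knockout C (adjusted p = 0.0669), with arrays centred on their medians (adjusted p = 0.560) and with arrays scaled to a common trimmed mean, where its direction turned (adjusted p = 0.809, median -0.01). Nqo1 read 9.10 in the array labelled knockout A, 8.48 in B and 8.22 in C, against a wild-type mean of 8.04.

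Of 8 small intestine and proximal gut genes 6 were higher, with a median of 0.26 (camera adjusted p = 0.00439; adjusted p = 0.287 with an estimated correlation). Rbp2 alone passed adjusted over the list alone and none passed over all genes. The transcription factor gene Pdx1 stood at 0.57 (SE 0.31) and Mgam, the maltase-glucoamylase gene, at 0.31 (SE 0.19), and both turn with the Gapdh ratio as a covariate, to -0.12 and -0.05. The call was lost without the array labelled knockout C (adjusted p = 0.753), without wild type B (adjusted p = 0.0623), with that covariate (adjusted p = 0.0834), with array weights (adjusted p = 0.124), with no filter on low values (adjusted p = 0.103) and on the signals as deposited (adjusted p = 0.064).

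Markers of squamous epithelium, a tissue at the anal end of the colon, were lower in 6 of 7 genes, with a median of -0.42 (camera adjusted p = 0.00439; adjusted p = 0.287 with an estimated correlation). The keratin gene Krt5 stood at -0.69 (SE 0.20) and Lor, the loricrin gene, at -0.48 (SE 0.22). Both lay close to the bottom of the scale, Krt5 at 5.40 in the arrays labelled knockout against 6.09 in wild type, and Lor at 5.67 against 6.15. The same held for Krt6a, at 5.31 against 5.73, for which another probe set went the opposite way. No member of the squamous list passed over all genes or adjusted over the list alone. This was the 1 list that fry called in a directional test (adjusted p = 0.0429), and the array means of the groups did not overlap. The camera call was lost with no filter on low values (adjusted p = 0.0672), with wild type B as the only control (adjusted p = 0.246) and with the Gapdh ratio as a covariate (adjusted p = 0.0828). Of 30 absorptive colonocyte genes 19 were lower, with a median of -0.09 (camera adjusted p = 0.0269; adjusted p = 0.796 with an estimated correlation), including Guca2a, which encodes guanylin, at -0.35 (SE 0.11) and the carbonic anhydrase gene Car4 at -0.68 (SE 0.36). Of 24 unfolded protein response genes 19 were lower, with a median of -0.06 (camera adjusted p = 0.0186; adjusted p = 0.796 with an estimated correlation), with Hyou1, an endoplasmic reticulum chaperone gene, at -0.64 (SE 0.29) and Calr, the calreticulin gene, at -0.25 (SE 0.12), the latter reading 0.17 on the signals as deposited, below the median of 0.43 for all genes there. No member of either list passed over all genes or adjusted over the list alone. The absorptive call was lost without the array labelled knockout A (adjusted p = 0.398), wild type A (adjusted p = 0.183) or wild type C (adjusted p = 0.355), with no filter (adjusted p = 0.0672), with wild type B as the only control (adjusted p = 0.109) and with the Gapdh ratio as a covariate (adjusted p = 0.6). The unfolded protein response call was lost without the array labelled knockout B (adjusted p = 0.130), wild type A (adjusted p = 0.233) or wild type B (adjusted p = 0.490), with no filter (adjusted p = 0.0793), with the mean of a gene's probe sets (adjusted p = 0.0643), with arrays centred on their medians (adjusted p = 0.345) and on the signals as deposited (adjusted p = 0.322). For the unfolded protein response list, the mean of the arrays labelled knockout differed by -0.30 from wild type B and by -0.05 from wild type A and C. Single arrays also weighed on Car4 and Hyou1. Car4 read 11.35 in the array labelled knockout A, 12.38 in B and 12.78 in C, against a wild-type mean of 12.85. Hyou1 read 9.93, 10.56 and 9.36 in wild type A, B and C, against a mean of 9.31 in the arrays labelled knockout. Of its 2 other probe sets 1 went the opposite way.

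**Figure D3:**
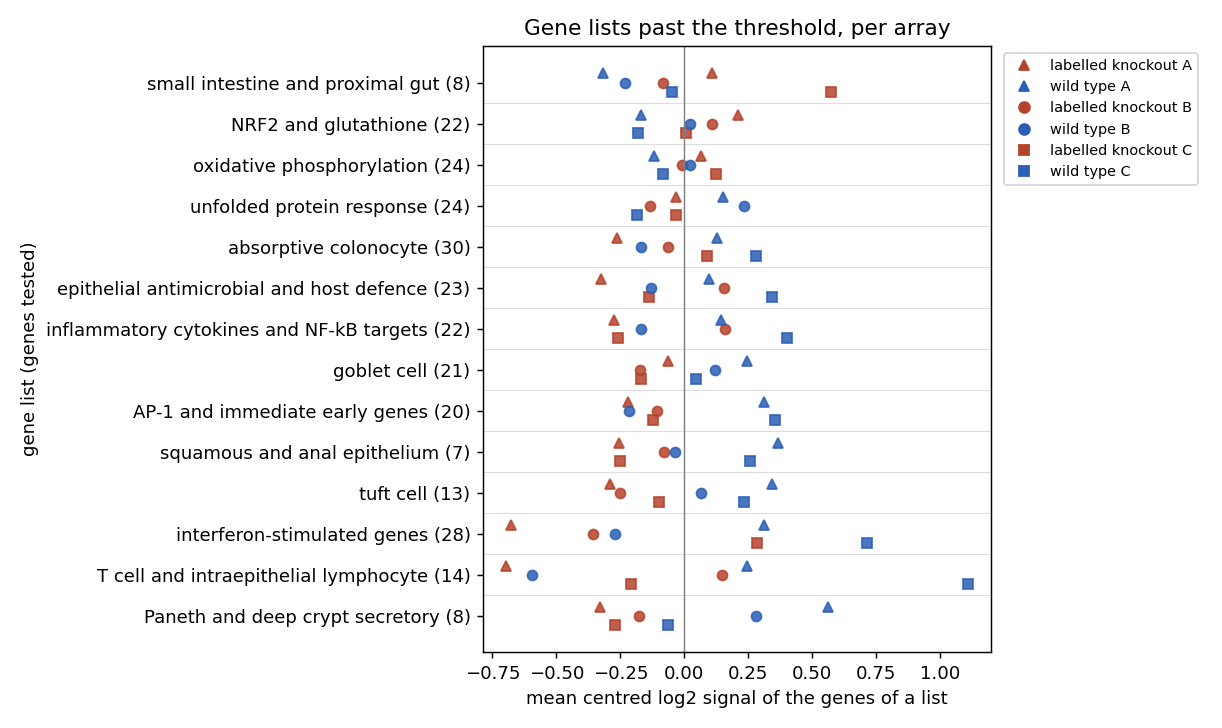
Each point is 1 array's mean over the tested genes of a list (number in brackets), after subtracting each gene's mean over the 6 arrays (x axis, log2), for the 14 lists called by camera (y axis). The groups lie apart for goblet, tuft, Paneth and squamous genes, while wild type B lies among the arrays labelled knockout for interferon-stimulated genes at -0.27 and below them, apart from A at -0.70, for T cell genes at -0.60.

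Of the 39 lists with at least 5 tested genes, camera called 14 with its preset correlation of 0.01, 3 higher and 11 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.287. fry, a directional test of each list alone, called 1. The other 25 lists had camera adjusted p-values from 0.0819 to 0.903.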

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

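The settings added after seeing the data were the common trimmed mean, wild type B as the only control and the Gapdh ratio as a covariate, and the cause of a change was not tested unless it is stated. Of 1654 values of 80 named genes under 21 alternatives, 20 changed sign, in 13 genes. Mapk14 stayed higher in the arrays labelled knockout under all 21 (0.32 to 0.94, limma adjusted p 0.00717 to 0.9999), as did Mt1 (2.14 to 2.72, past the threshold in 8, adjusted p 1.75e-05 to 0.803), and Clps stayed lower (-2.25 to -1.58, past the threshold in 1). limma called 0 genes at first, with 490 at an unadjusted p under 0.05. On the signals as deposited it called 1, with 120 genes at least 2-fold apart and separate instead of 36, and Mapk13 (0.27), Dnajb9 (0.068), Calr (0.171) and Ern2 (0.182) changed sign, a shift of all genes by 0.43 being part of that setting. limma called 1 gene with arrays centred on their medians and 1 with a pseudocount of 64. The 2-fold count was 90 with a pseudocount of 1 and 18 with 64, since the pseudocount sets how far dim genes can differ. With array weights limma called 2722 genes (Mapk14 at 0.503, adjusted p 0.00717) and the 2-fold count was 61, but the weights did not converge and gave wild type A a weight of 33.5 against 0.195 to 1.39 for the others. With the common trimmed mean Uqcrc2 changed sign (-0.017). With wild type B as the only control, whose spread is then assumed to equal that of the arrays labelled knockout, limma called 1 gene, the 2-fold count was 125, and Mapk13 (0.237), Cd3d (0.262), Cd3g (0.465), Cd8a (0.302) and Dusp1 (0.03) changed sign. With the Gapdh ratio as a covariate Mapk12 (0.131), Mapk13 (0.359), Cd3d (0.475), Cd3g (0.595), Cd8a (0.504), Pdx1 (-0.119), Mgam (-0.054), Cdhr5 (0.051) and Dusp1 (0.071) changed sign. Leaving out 1 array at a time, limma called 0 to 6 genes, the 2-fold count ran from 44 to 267, partly because groups of 2 against 3 separate more easily, and Mapk13 ran from -0.395 to 0.128. camera called 12 to 18 lists under the 21 settings, with an estimated correlation 0 and with fry 1 instead of 14. Of the 14 lists, 6 were still called with wild type B as the only control and 5 with the covariate, counting calls in either direction. Signal over background limits the dim genes, since 40% of probe sets lay under a signal of 18.4.

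The replicate letters are shared by the groups, and whether they pair the samples is not known. The correlations below rest on 3 arrays per group, too few to show or exclude a pairing. The deviations of same-letter arrays from their group means correlated at -0.0418 for A, -0.111 for B and 0.452 for C, while the array labelled knockout A correlated best with wild type B, at 0.514. With the replicate block limma called 3 genes, Mt1, Pla2g4c and Pnliprp2, instead of 0, and camera called 17 lists instead of 14, all 14 among them and proliferation, smooth muscle, and tight junction genes added; the block changed no other call of a list.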

Other observations

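Chosen only after the results were seen were the splits, the relations, the settings with wild type B as the only control or the Gapdh ratio as a covariate, and the tests of explanations other than the one on the genes around Mapk14. The list of clock genes was not called (17 genes, 10 higher and 7 lower, camera adjusted p = 0.783), and no member passed over all genes tested or adjusted over the list alone. In that test members moving in opposite directions offset each other, so it does not tell whether clock genes differed. At an unadjusted limma p under 0.05, 2 members were higher and 3 lower. Nr1d2 stood at 0.95 (SE 0.27) and Per3 at 0.75 (SE 0.31). Nfil3, a repressor of clock output genes, stood at -1.10 (SE 0.31), Cry1 at -0.79 (SE 0.25) and Npas2 at -0.58 (SE 0.20). Enteroendocrine genes, markers of the hormone-secreting cells, split as well: Nts (neurotensin) stood at -1.30 (SE 0.51), Chga at -1.27 (SE 0.69), Tph1, the enzyme gene of serotonin synthesis, at -1.25 (SE 0.61) and Neurod1 at -0.66 (SE 0.27), against Scg2 at 0.47 (SE 0.20). That list's median was 0.03, its mean -0.22 and its test pointed lower (camera adjusted p = 0.543).

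Of 26 proliferation genes 19 were higher, with a median of 0.24 (camera adjusted p = 0.151), but the list was called lower with wild type B as the only control (adjusted p = 2.86e-07) and with the Gapdh ratio as a covariate (adjusted p = 1.59e-07), and without wild type C (adjusted p = 0.0301), and higher without wild type B (adjusted p = 0.000292), without the array labelled knockout C (adjusted p = 0.00354) and with every probe set tested (adjusted p = 0.0236). Calls for the lists of other cell types depended on the setting. Smooth muscle genes (camera adjusted p = 0.0947) were called higher with no filter (0.00498), without the arrays labelled knockout B (0.00674) or C (0.0157), without wild type A (0.0174) or C (0.0248), with wild type B as the only control (0.00508) and with the covariate (0.0345). Fibroblast genes (0.315) were called lower on the signals as deposited (0.00684), centred on array medians (0.0329) and without the array labelled knockout B (0.000705). B and plasma cell genes (0.827) were called lower without wild type B (0.031), and higher with it as the only control (1.64e-06) and with the covariate (0.000437), and macrophage and dendritic cell genes (0.627) higher in these last settings (0.00181 and 0.00188). The median and the test differed in sign for the ERK feedback, heat shock and enteric neuron lists (medians 0.06, 0.01 and -0.14), of which none was called. Mt2, the metallothionein gene next to Mt1, stood at 0.83 (SE 0.23), with no overlap between the groups. Chosen after their values were seen, Cd274 stood at -1.51 (SE 0.42), Ido1 at -1.49 (SE 0.39) and Prdm1 at -1.43 (SE 0.44), none of which passed (limma adjusted p = 0.902 each), and for Cd274 and Prdm1 wild type B (6.97 and 6.79) lay nearer to the arrays labelled knockout (6.52 ± 0.28 and 6.49 ± 0.17, SD, n = 3) than wild type A (8.44 and 8.39) did.

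Mapk14 signal on the brightest probe set was higher, not lower, in the arrays labelled knockout. An exchange of labels between some arrays of the groups would mix them if the probe set reads the deleted part, and the lowest array labelled knockout lay 0.28 above the highest wild-type array, beyond the larger group SD of 0.11, but the groups overlap on the other Mapk14 probe sets and which of them read the deleted part is not known, so a partial exchange cannot be told apart. With the Gapdh ratio as a covariate the difference stayed at 0.416 (SE 0.197), but its 95% interval, -0.04 to 0.87, reaches below 0, so lower RNA quality of wild type A and C stays open. Probe sets outside the deleted part may account for a signal in a true knockout, and this cannot be told apart, because 0 of the Mapk14 probe sets could be placed against the deleted part with what was used here. An exchange of all labels, and transcripts from cells that kept the gene, were not tested.

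Goblet and tuft lists, and interferon, T cell and AP-1 lists, were lower in the arrays labelled knockout. The Gapdh ratio, the measure of RNA quality used, moved with the groups, while the Actb ratios of the groups overlapped. With the Gapdh ratio as a covariate the goblet and tuft medians went from -0.24 to -0.36 and from -0.42 to -0.34, and both lists stayed called and lower with camera's preset correlation (larger adjusted p = 0.00164, range over the settings 3.56e-09 to 0.0116 for tuft genes), but with an estimated correlation neither was called with the covariate (adjusted p = 0.464 and 0.573) or without it (0.287 each), nor by fry with it (0.422 and 0.695). The mean of the goblet list in the arrays labelled knockout differed by -0.25 from wild type B and by -0.28 from wild type A and C, and that of the tuft list by -0.28 and -0.50, but wild type B is 1 array, and the array means separated the groups in both of these 2 lists and in 4 of the 39 tested, where chance gives 10%, so lower RNA quality of wild type A and C and genotype cannot be told apart there. Of the interferon, T cell and AP-1 lists, 0 of 3 stayed called and lower with the covariate, the median of the interferon list going from -0.40 to -0.09 and the T cell list being called higher (adjusted p = 3.59e-05), and RNA quality cannot be told apart from genotype there because the covariate differs between the groups. Local inflammation or a different share of immune cells in wild type A and C was not tested.

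Clps, which was 4.11-fold lower, lies near Mapk14 on the chromosome, with 1 tested gene between them, so flanking DNA of another strain is a candidate explanation. The 50 tested genes around Mapk14 had a median absolute t of 0.767, at the 41.4th percentile of 11410 such windows, which argues against flanking DNA that shifts most genes around Mapk14. A median over 50 genes would not register flanking DNA that shifts only a few of them, so that stays open. A variant in flanking DNA acting on Clps alone stays open and cannot be told apart from an effect of genotype, since Clps was the 1 gene of that window at an unadjusted p under 0.05 and no sequence of the allele was used here. Traces of pancreas in wild type A and C are argued against, because the median difference of 8 other pancreatic enzyme genes there was -0.118 (SD 0.365) while that of Clps was 2.05. Pancreas transcripts were present in wild type B, where Prss2 read 200 and Cela2a 206, against at most 19.3 and 18.3 in the other 5 arrays.

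The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. For genes called by limma the real split gave 0, the highest other 0, and all 10 splits gave as many. For genes at least 2-fold apart and separate the real split gave 36, the highest other 213, and 5 of 10 gave as many. For lists called by camera the real split gave 14, the highest other 18, and 4 of 10 gave as many. The split of the arrays labelled knockout A and B with wild type B against the rest gave 2674 genes at an unadjusted p under 0.05, against 490 for the real split, and 0 past the threshold. It was singled out as the largest of the 10, and a structure of the samples other than the genotype labels, to which such a count may point, was not tested.

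Across the 6 arrays 6 relations between list means or the Gapdh ratio were computed, each with exact permutation tests, and each group's 3 arrays are too few to repeat them within a group. For the means of B and plasma cell genes and of macrophage genes r passed after adjustment and rho did not (r = 0.959, p = 0.00417, adjusted 0.025; rho = 0.943, p = 0.0167, adjusted 0.1), and r was 0.788 without the array labelled knockout A and wild type B. The other 5 relations did not pass after adjustment. For T cell and interferon-stimulated genes r was 0.808 (p = 0.0444, adjusted 0.0666; rho = 0.829, p = 0.0583, adjusted 0.175), and r was 0.301 without the array labelled knockout A and wild type C, on which the value rests. For T cell genes and the log2 Gapdh ratio r was 0.856 (p = 0.0389, adjusted 0.0666; rho = 0.714, p = 0.136, adjusted 0.204), with r = 0.645 without the array labelled knockout C and wild type C. For T cell and proliferation genes r was -0.886 (p = 0.0208, adjusted 0.0624; rho = -0.771, p = 0.103, adjusted 0.204), with r = -0.554 without the array labelled knockout A and wild type C. The log2 Gapdh ratio had r = 0.688 with interferon-stimulated genes (p = 0.106, adjusted 0.127; rho = 0.657, p = 0.175, adjusted 0.21; r = 0.995 without the array labelled knockout C and wild type C) and r = -0.691 with proliferation genes (p = 0.129, adjusted 0.129; rho = -0.257, p = 0.658, adjusted 0.658; r = -0.614 without these).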
